A study of Homo sapiens with 27 samples.

How the data were processed

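Total RNA of MDA-MB-231 cells, a human breast cancer line, was measured on Affymetrix arrays named HG-U133A+2 in the labels, after treatment with DMSO as the vehicle, with 5SGlcNAc at 50 µM, an inhibitor of O-GlcNAc transferase (OGT), or with Thiamet-G at 25 µM, an inhibitor of O-GlcNAcase (OGA). The labels give 27 arrays. Of these, 18 are single arrays, 1 per treatment at 0, 2, 4, 6, 8 and 24 h, and 9 are arrays of 48 h, 3 per treatment. The deposited values are log2 expression levels per probe set, made with RMA, per the submitters' processing notes, which give no version. RMA subtracts a modelled background, equalises the distributions of the arrays processed together and summarises the probes of a set, so it can hide a change that moves most genes one way.

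The deposited log2 values fall into 2 sets. The 48 h arrays are given to 2 decimals with array medians of 7.68 to 7.76, and the arrays of 0 to 24 h to 6 decimals with medians of 7.43 to 7.53. Levels of 48 h arrays were therefore never set against levels of other times, and each test used arrays of 1 set, apart from a test of the difference between effects within each set. The lowest correlation between arrays was 0.997 within the 48 h set and 0.994 within the other. No array columns were identical. The number of arrays limits the precision. At 48 h the median standard error of a log2 fold change was 0.0615. Nothing in the labels says that the 48 h replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

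Of 22277 probe sets, 62 were controls, 19064 named 1 gene in the platform annotation, 1043 named several and 2108 none. Symbols were updated through Entrez identifiers, which matched for 19052 probe sets. Probe sets naming several genes or none were left out of gene tests. Each of 11963 genes was represented by the probe set with the highest mean over the arrays of the fit. Of these genes, 4310 had over 1 probe set. No filter on dim genes was used.

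Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at a threshold of 0.05. At 48 h, all 9 arrays shared 1 estimate of the spread. Over 2 to 24 h, the mean effect of each inhibitor was tested across 5 times with time as a block, so that the times stood in for replicates. Changes with time were tested against 0 h with the 3 treatment series as a block. Values at a single time of 0 to 24 h have 1 array per treatment and no test. Gene lists were tested with camera of limma at a preset correlation of 0.01, with an estimated correlation beside it, adjusted over 32 lists of pathways and cell type markers. The lists included markers of haematopoietic cells, luminal epithelium and fibroblasts as cell types other than the studied line.

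Genes were named by a rule. For each 48 h contrast it took the 6 largest rises and 6 largest falls among genes past the threshold with non-overlapping replicates. It also took up to 3 members with the largest change from each list past the camera threshold. Genes always named were OGT, OGA, NFE2L2, KEAP1, NQO1, HMOX1, GCLM, GCLC, TXNRD1, SLC7A11, TXNIP and SRXN1, of which SRXN1 was not measured by a probe set naming 1 gene. Over 2 to 24 h it took the 5 largest rises and falls with 1 sign at all times, or the 5 smallest p in each direction where fewer than 10 genes passed. For time it took the 4 largest rises and falls with 1 sign in all series, and for single arrays at 24 h the 5 largest differences among genes above the median level. A list named for another reason could have up to 3 members with the smallest p named. The groups, tests, lists, rule and most alternatives were fixed before the data were examined. Added after seeing the data were fits without the DMSO array of 4 h, median centring of single arrays for the 48 h genes by direction, list tests at 2 to 8 h against 0 h, the test of 48 h effects against 2 to 24 h effects, and camera tests of 149 gene families that share the first letters of their symbols. At the preset correlation COL and MCM (medians -0.10 and -0.10) passed as lower with 5SGlcNAc at 48 h against DMSO. KIR (0.15) and OR (0.08) passed there as higher, and MT (0.24) at 24 h against 0 h. No family passed with an estimated correlation.

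Alternatives were quantile normalization, median centring, a filter on dim genes under the 40th percentile, the mean of a gene's probe sets, leaving out probe sets of shared sequence (those ending in _x_at), trend and robust variance, only the arrays of the 2 groups, replicate number as a block, other blocks and sets of times, and leaving out each array, time or series. The gene tests were run on simulated data with 200 changed genes among 11963. For 5SGlcNAc against DMSO at 48 h, 65.7% of genes changed by 0.3 on the log2 scale were called, 89.6% of those changed by 0.6 and 100% of those changed by 1.2, and unchanged genes made up 5.03% of calls. Over 2 to 24 h, 76.1%, 97.0% and 100% were called for the same comparison, with 2.15% of calls unchanged. There the simulated effect was the same at every time, so these shares do not hold for an effect limited to late times. For 24 h against 0 h, 40.3%, 91.0% and 100% were called, with 3.75% unchanged. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.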

Results

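The series measured messenger RNA in MDA-MB-231 cells, an invasive breast cancer line, after inhibition of the enzymes that add and remove O-GlcNAc, a single sugar on serine and threonine residues of intracellular proteins. 5SGlcNAc inhibits OGT, which adds the sugar, and Thiamet-G inhibits OGA, which removes it. The series' title names the transcription factor NRF2 and its inhibitor KEAP1, so the first question was whether either inhibitor changed NRF2 target genes. At 48 h there were 3 arrays each for DMSO, 5SGlcNAc and Thiamet-G. At 0, 2, 4, 6, 8 and 24 h there was 1 array per treatment. The 3' minus 5' signal of ACTB, a measure of RNA integrity, was 0.15 to 0.39 on the log2 scale at 48 h, and was 1.64 in the DMSO array of 4 h and 1.24 in the Thiamet-G array of 4 h. In the other arrays of 0 to 24 h it was 0.42 to 0.95. The same signal of GAPDH was 0.11 to 0.27 over all arrays and did not set the 4 h arrays apart.

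With 5SGlcNAc for 48 h, NRF2 target genes rose together. HMOX1, which degrades haem, rose from 8.75 ± 0.051 to 11.11 ± 0.051 (SD, n = 3) on the log2 scale, a 5.13-fold increase. NQO1, a quinone reductase, rose by 1.07, GCLM and GCLC, the subunits of the enzyme that starts glutathione synthesis, 2.30-fold and by 0.60 on the log2 scale, SLC7A11, the cystine transporter, by 0.95, and TXNRD1, thioredoxin reductase, by 0.72. TRIM16 rose by 1.47. Of 36 measured members of the NRF2 list, 25 rose, 1 fell (CBR3, a carbonyl reductase, fell by 0.25) and 10 did not pass. Adjusted over the list alone, 28 rose and 2 fell. The median change was 0.30, camera gave an adjusted p = 2.94e-20, and the adjusted p was 0.00481 with an estimated correlation. NFE2L2, the gene of NRF2 itself, differed by 0.01 ± 0.061 (SE; adjusted p = 0.938, limma) and KEAP1 by 0.09 ± 0.041 (adjusted p = 0.193).

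**Figure D1:**
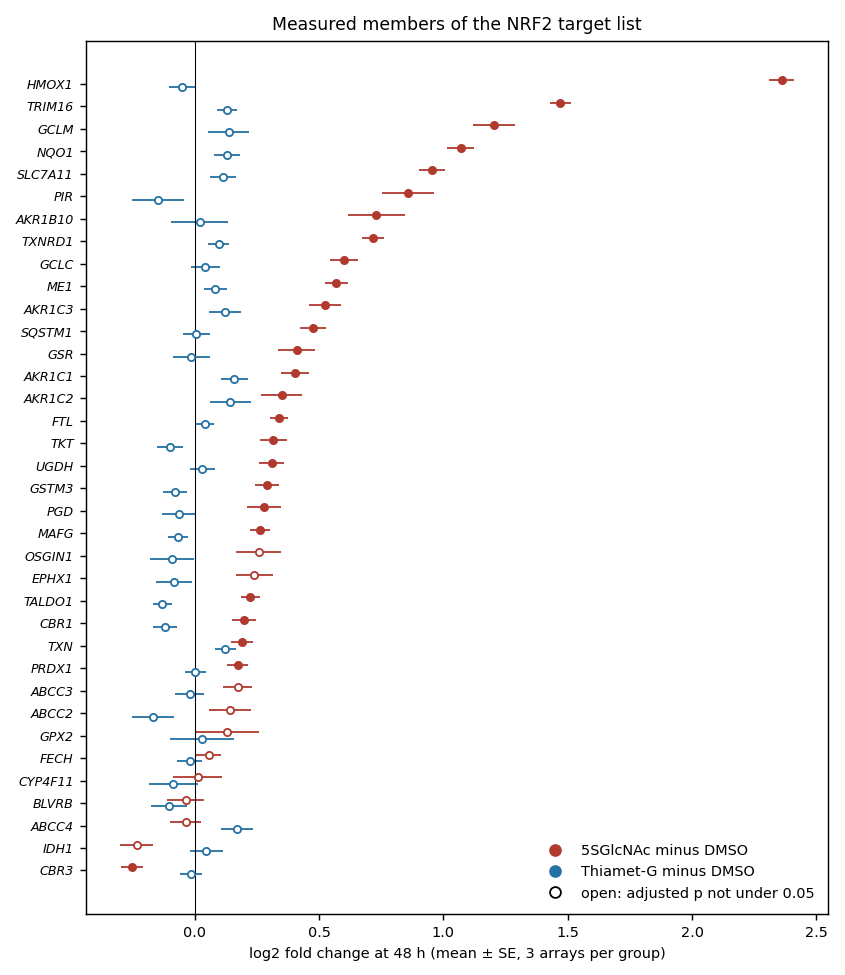
Log2 fold change at 48 h (x axis, mean ± SE, 3 arrays per group) of the 36 measured NRF2 targets (y axis) for 5SGlcNAc (red) and Thiamet-G (blue) against DMSO, with open points where limma's adjusted p was not under 0.05. HMOX1 lies at 2.36 with 5SGlcNAc and at -0.05 with Thiamet-G, and all 36 Thiamet-G points are open.

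The cycling enzymes responded as well. OGA fell by 1.08 with 5SGlcNAc (adjusted p = 4.16e-06), and its second brightest probe set fell by 0.99. The brightest probe set of OGT rose by 0.86 (adjusted p = 1.46e-05), but the second and the fourth brightest fell by 1.70 and 1.40, and the mean of its 5 probe sets fell by 0.43. No single direction can therefore be given for OGT messenger RNA. In the list of O-GlcNAc cycling and the hexosamine pathway, 1 of 8 members rose, 2 fell and the list did not pass (adjusted p = 0.720), with a median of 0.06 and a mean of -0.01. The member counted as risen was OGT by its brightest probe set, so these list values rest in part on the choice of that probe set. Adjusted over the list alone, 2 rose and 2 fell. GNE, an enzyme of sialic acid synthesis, was the other member that fell, by 0.22.

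In the NF-kB, matrix and interferon lists, more members fell than rose with 5SGlcNAc. The largest falls outside the lists were SLCO4A1, an organic anion transporter, by 1.44 ± 0.066 (SE, n = 3), AGR2, a disulfide isomerase, by 1.30, NNMT, nicotinamide N-methyltransferase, by 1.16, NDP by 1.10 and APOBEC3G, a cytidine deaminase, by 1.09. A dimmer probe set of APOBEC3G differed by -0.02. In the NF-kB list, 8 of 20 members fell and 1 rose, the same counts as adjusted over the list alone. PTGS2, the inducible cyclooxygenase, fell by 0.78, and the chemokines CXCL2 and CXCL1 fell by 0.75 and 0.65. IL11, named after its value was seen, rose by 0.27. The list passed (adjusted p = 0.000381, and 0.0482 with an estimated correlation). In the list of epithelial to mesenchymal transition and matrix, 11 of 28 fell and none rose, and 15 fell and 1 rose adjusted over the list alone. COL6A3, a collagen, fell by 0.74, the matrix protein TNC by 0.56 and the protease PLAU by 0.55. CDH1, the epithelial cadherin, which is lost in that transition, also fell, by 0.29. That list gave an adjusted p = 0.000125, and 0.0482 with an estimated correlation. In the interferon list, 15 of 26 fell and none rose (18 and 0 adjusted over the list alone), among them TRIM22 by 0.54, IFIT3 by 0.46 and IRF7 by 0.46. Its camera adjusted p = 1.46e-08 became an adjusted p = 0.0789 with an estimated correlation.

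Cell cycle and signalling lists also shifted down. For DNA replication, 9 of 30 members fell and none rose (14 and 0 adjusted over the list alone), and MCM7, a replicative helicase subunit, fell by 0.77, TK1, thymidine kinase, by 0.47 and CHAF1B by 0.34. The adjusted p was 1.14e-06, but the adjusted p = 0.0691 with an estimated correlation. For mitosis, 13 of 31 fell and none rose (20 and 0 adjusted over the list alone), among them CDC25C by 0.27, NUSAP1 by 0.26 and KIF20A by 0.26 (adjusted p = 1.50e-09, and adjusted p = 0.0789 with an estimated correlation). For ERK feedback, 7 of 13 fell and none rose (9 and 0 adjusted over the list alone), led by the phosphatases DUSP4 by 0.47 and DUSP6 by 0.35, and by ETV4 by 0.32 (adjusted p = 1.47e-05, and adjusted p = 0.0789 with an estimated correlation). Among ER chaperones, HSP90B1 fell by 0.36, PDIA4 by 0.24 and HERPUD1 by 0.19, and DNAJB9, named after its value was seen, rose by 0.17. These were the 4 of 18 members that passed, against 7 falls and 1 rise adjusted over the list alone (adjusted p = 0.000136, and 0.0482 with an estimated correlation). In the cholesterol list, INSIG1 fell by 0.49, the synthase HMGCS1 by 0.47 and the regulator SREBF2 by 0.28. These were the 3 of 18 that passed, against 4 adjusted over the list alone (adjusted p = 0.0207, and adjusted p = 0.454 with an estimated correlation).

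Ribosome biogenesis, proteasome and heat shock lists shifted up. For ribosome biogenesis, 10 of 19 rose and none fell (13 and 0 adjusted over the list alone), led by BYSL by 0.34, NOP16 by 0.30 and WDR43 by 0.29 (adjusted p = 4.52e-08, and adjusted p = 0.0789 with an estimated correlation). For the proteasome, 6 of 28 rose and none fell (12 and 0 adjusted over the list alone), with PSMD4 higher by 0.19, PSMD11 by 0.18 and PSMB5 by 0.18 (adjusted p = 5.94e-06, and adjusted p = 0.0789 with an estimated correlation). Among 15 heat shock genes, CHORDC1 rose by 0.26 and DNAJA1 by 0.18, and 4 rose adjusted over the list alone (adjusted p = 0.000708, and adjusted p = 0.0691 with an estimated correlation). TXNIP, an arrestin that binds thioredoxin, fell by 0.21. Of the markers of other cell types, none of 10 haematopoietic genes changed, also adjusted over the list alone (median 0.04, adjusted p = 0.720). The fibroblast genes COL6A3 and LUM fell, the latter by 0.49 and named after its value was seen, and 11 of 13 did not pass; 3 fell adjusted over the list alone (adjusted p = 0.853). That list's median was 0.02 and its mean -0.03. In the luminal list CLDN7, KRT19 and CDH1 fell, by 0.48, 0.42 and 0.29, and 15 of 18 did not pass, with the same 3 falls counted adjusted over the list alone (adjusted p = 0.00161, and adjusted p = 0.0789 with an estimated correlation).

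In all, 1225 of 11963 genes changed with 5SGlcNAc at 48 h (limma, adjusted), 349 up and 876 down, and 75 changed over 1.5-fold. Over all genes tested, the 3 treated and 3 DMSO arrays did not overlap for 3737 (31.2%), where chance gives 10%. The share that fell was 71.5% as deposited, 759 of 1265 calls after quantile normalization and 58.7% after median centring. Leaving out 1 of the 6 arrays gave 679 to 984 genes, and the lowest count was without 5SGlcNAc replicate 1; without DMSO replicates 1, 2 and 3 the counts were 782, 718 and 810, and without 5SGlcNAc replicate 2 it was 749.

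**Figure D2:**
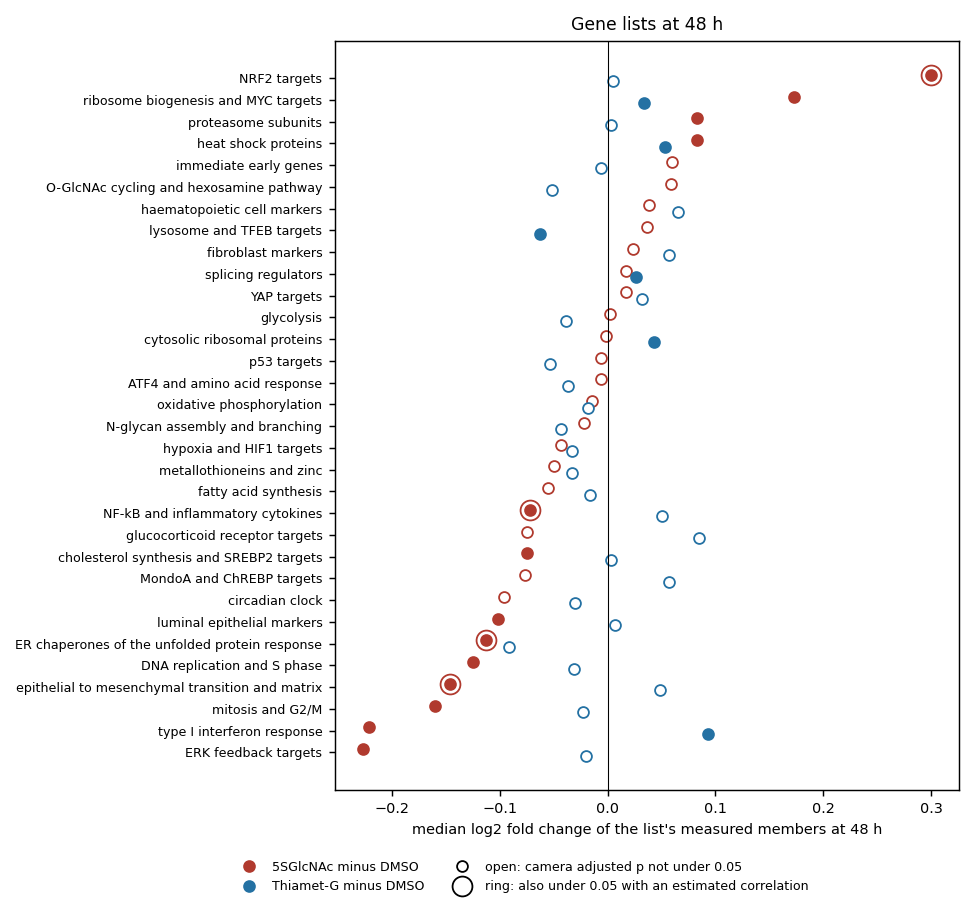
Median log2 fold change of each of 32 gene lists at 48 h (x axis; lists on the y axis) for 5SGlcNAc (red) and Thiamet-G (blue) against DMSO. Filled points had a camera adjusted p under 0.05, and rings mark the 4 lists, all with 5SGlcNAc, that also passed with an estimated correlation; NRF2 targets lie at 0.30 with 5SGlcNAc.

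Thiamet-G for 48 h left the NRF2 list without a called member. None of 36 passed in limma, over all genes or adjusted over the list alone, and 2373 of all genes had an unadjusted p under 0.05. The list median was 0.005 (adjusted p = 0.361). NQO1 differed by 0.13 ± 0.054 (SE, n = 3; adjusted p = 0.223), HMOX1 by -0.05, GCLM by 0.14, GCLC by 0.04, TXNRD1 by 0.10, SLC7A11 by 0.11, TXNIP by 0.06, NFE2L2 by 0.01 and KEAP1 by -0.15 (adjusted p = 0.0938). OGA rose by 0.62 (adjusted p = 0.000912), and its second brightest probe set rose by 0.56. The brightest OGT probe set fell by 0.24 (adjusted p = 0.0217), while the second and the fourth differed by 0.17 and 0.15, so that the mean of OGT probe sets lay at 0.06.

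Other genes that rose with Thiamet-G were SPP2 by 0.54, the stress-induced transcription factor ATF3 by 0.54, the metalloprotease ADAMTS1 by 0.46, the transcriptional regulator CITED2 by 0.42 and FRMD4B by 0.42. PCYOX1L fell by 0.95 ± 0.060 (SE, n = 3), GUCY1B1, a subunit of soluble guanylate cyclase, by 0.75, RNFT2 by 0.71, TMEM187 by 0.69, IFT27, a protein of intraflagellar transport, by 0.69 and RAB40B by 0.65. A dimmer probe set differed by -0.003 for IFT27, by -0.17 for RAB40B and by -0.05 for FRMD4B. Those of CITED2 (0.21), GUCY1B1 (-0.52) and RNFT2 (-0.58) lay nearer to the values given. Of 32 lists, 6 passed at the preset correlation and none with an estimated one. The number was 3 after quantile normalization or without DMSO replicate 1, and 2 without Thiamet-G replicate 3. The interferon list had a median of 0.09 and shifted up (adjusted p = 0.00760, and adjusted p = 0.509 with an estimated correlation), although its only called member, IRF7, fell by 0.28; adjusted over the list alone, 1 rose and 1 fell. The heat shock list shifted up (adjusted p = 0.0260, and adjusted p = 0.371 with an estimated correlation), with CHORDC1 higher by 0.27 as its only called member, also adjusted over the list alone. The lysosome list shifted down (adjusted p = 0.0260, and adjusted p = 0.371 with an estimated correlation), where the lysosomal cation channel MCOLN1 fell by 0.22 as the only called one of 24 members and 5 falls adjusted over the list alone. Cytosolic ribosomal proteins (median 0.04), ribosome biogenesis (0.03) and splicing regulators (0.03) shifted up with no called member, over all genes or adjusted over the list alone. Their adjusted p values were 0.00801, 0.0260 and 0.0260, and adjusted p = 0.371, 0.555 and 0.530 with an estimated correlation. Their medians were 0.08, 0.07 and 0.07 after median centring and 0.03, 0.06 and 0.03 after quantile normalization, where these 3 lists and the heat shock list no longer passed. Haematopoietic, luminal and fibroblast markers did not pass (adjusted p = 0.731, 0.844 and 0.696), and the luminal median of 0.01 and mean of -0.01 differed in sign.

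With Thiamet-G 417 genes changed, 57 up and 360 down, and 7 over 1.5-fold. Over all genes tested, 2573 (21.5%) had non-overlapping arrays, where chance gives 10%. The share that fell was 86.3% as deposited, 73.6% after quantile normalization and 74.5% after median centring, and the last gave 235 genes. The count was 129 with only the arrays of the 2 groups, 949 without dim genes and 925 with trend and robust variance. It was 101 without DMSO replicate 3, 683 without Thiamet-G replicate 2, and 122 to 166 without any other 1 of the 6 arrays.

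The inhibitors differed directly from each other at 48 h in the NRF2 list. Of 36 members, 26 were higher with 5SGlcNAc and 2 lower (CBR3 at -0.24, and IDH1, which was named after its value was seen, at -0.28); adjusted over the list alone 28 were higher and 3 lower. The list median was 0.34, with an adjusted p = 3.31e-16, and 0.00896 with an estimated correlation. HMOX1 was higher by 2.41, TRIM16 by 1.34, GCLM by 1.07, NQO1 by 0.94, SLC7A11 by 0.84, TXNRD1 by 0.62 and GCLC by 0.56. PIR lay at 8.25 with 5SGlcNAc and 7.24 with Thiamet-G. KEAP1 was higher by 0.24 ± 0.041 (SE, n = 3; adjusted p = 0.00553) with 5SGlcNAc than with Thiamet-G, although it passed in neither contrast against DMSO, and NFE2L2 had a confidence interval of -0.14 to 0.14. The brightest OGT probe set was higher by 1.10, and the second and the fourth were lower (difference -1.87 and -1.55). OGA was lower with 5SGlcNAc, with a difference of -1.70.

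In the NF-kB, matrix and interferon lists, more members passed as lower than as higher with 5SGlcNAc than with Thiamet-G. In the NF-kB list 10 of 20 members were lower with 5SGlcNAc and 1 higher (IL11, with a difference of 0.46, named after its value was seen), the same counts as adjusted over the list alone. The cytokine IL6 differed by -0.84, CXCL1 by -0.73 and PTGS2 by -0.73 (list adjusted p = 3.48e-06, and 0.0173 with an estimated correlation). In the matrix list 12 of 28 were lower and none higher (13 and 0 adjusted over the list alone), with TIMP3 at -0.57, PLAU at -0.55 and MMP1 at -0.52; CDH1, the epithelial member, was at -0.34 (adjusted p = 4.77e-07, and 0.0140 with an estimated correlation). In the interferon list 16 of 26 were lower and none higher (20 and 0 adjusted over the list alone), with TRIM22 at -0.77, IFIT1 at -0.75 and IFIT3 at -0.58 (adjusted p = 3.47e-14, and adjusted p = 0.0699 with an estimated correlation). SLCO4A1 (-1.51), AGR2 (-1.47), NNMT (-1.34), IGFBP1 (-1.12) and APOBEC3G (-1.05) were the lowest genes after OGA. For APOBEC3G, the fit on only these 6 arrays took its other probe set, which differed by 0.08.

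In the remaining lists past the preset threshold, lower members with 5SGlcNAc than with Thiamet-G included the replication genes MCM7 (-0.69), TK1 (-0.40) and POLE2 (-0.28), the mitotic genes ECT2 (-0.42), KIF23 (-0.39) and KIF20A (-0.35), and the ERK feedback genes DUSP4 (-0.49), DUSP6 (-0.44) and SPRY2 (-0.30). HMGCS1 (-0.78) and INSIG1 (-0.53) of the cholesterol list, CEBPD (-0.50), KLF9 (-0.47) and TSC22D3 (-0.28) of the glucocorticoid receptor list, and KRT19 (-0.46), CLDN7 (-0.46) and CDH1 of the luminal list were lower too. Dimmer probe sets of the glucocorticoid genes differed by -0.09 for CEBPD, 0.13 for TSC22D3, and -0.94 and 0.26 for KLF9. Members that went against their lists were PMVK of cholesterol synthesis (0.51) and, named after their values were seen, the mitotic gene HMMR (0.24), the replication gene ORC1 (0.25) and the lysosomal proteases CTSB (-0.23) and CTSS (-0.36). Higher members were BYSL (0.33), NOP16 (0.31) and RRP9 (0.31) of ribosome biogenesis, PSMD4 (0.27), PSMD3 (0.25) and PSMA5 (0.17) of the proteasome, and GLA (0.49), SQSTM1 (0.47) and CTSL (0.43) of the lysosome list. SQSTM1 is also in the NRF2 list. Cytosolic ribosomal proteins passed with no called member (median -0.03, adjusted p = 0.0366) and lost the call after quantile normalization. In the order replication, mitosis, ERK feedback, cholesterol, glucocorticoid, luminal, ribosome biogenesis, proteasome and lysosome, camera gave adjusted p = 3.48e-06, 2.53e-09, 7.37e-05, 0.00879, 0.0137, 0.00330, 0.00157, 0.000308 and 0.0284. None of these lists held with an estimated correlation. In the same order, with ribosomal proteins last, adjusted p = 0.102, 0.116, 0.138, 0.348, 0.116, 0.116, 0.269, 0.194, 0.234 and 0.348 with an estimated correlation. Members that passed were 9 of 30, 14 of 31, 7 of 13, 7 of 18, 3 of 8, 5 of 18, 9 of 19, 9 of 28, 9 of 24 and 0 of 28, and adjusted over the list alone 15, 19, 8, 8, 3, 5, 9, 12, 13 and 0. In all 1634 genes differed, 822 higher and 812 lower with 5SGlcNAc, 90 of them over 1.5-fold. Over all genes tested, 3500 (29.3%) had non-overlapping arrays, where chance gives 10%. The count was 926 without 5SGlcNAc replicate 1, 1074 without 5SGlcNAc replicate 2 and 1038 without Thiamet-G replicate 1, and 1069 with only the arrays of the 2 groups. After median centring, 56.5% of 1465 genes were lower, against 49.7% as deposited.

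Some genes were called with both inhibitors against DMSO. Both raised 16 genes, among them ATF3 (0.29 with 5SGlcNAc and 0.54 with Thiamet-G), CHORDC1 and ADAMTS1, and both lowered 98, among them IRF7 and COL6A3. A further 11 rose with 5SGlcNAc and fell with Thiamet-G, and 13 fell with 5SGlcNAc and rose with Thiamet-G, among them OGA and IL6 (fell by 0.60, and 0.24). After quantile normalization the genes shared in direction numbered 71 in place of 114. Independent lists of these sizes, as deposited, would share 1.66, 26.4, 10.5 and 4.17 genes. Fold changes correlated across genes, which are not independent replicates, at 0.316, against 0.500 in simulated unchanged groups that shared the DMSO arrays. The covariance was 0.0059 against 0.0032 simulated. With 3 DMSO arrays the controls cannot be split into groups of at least 2, so part of the excess may come from the shared controls. The shared genes given here were chosen after their values were seen.

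The time course asked when these differences appeared. At 24 h, with 1 array per treatment and no test, HMOX1 was 11.04 with 5SGlcNAc and 8.73 with DMSO, GCLM 12.48 and 11.32, and NQO1 12.57 and 12.25. OGA was 8.69 against 10.74. The brightest OGT probe set differed by 1.21 and the second by -2.19. At 8 h the 5SGlcNAc array was at 8.83 for HMOX1 against 8.53 with DMSO, and at 9.92 for OGA against 10.82. The other largest differences at 24 h with 5SGlcNAc were SLCO4A1 (-1.07), CYP1A1 (-1.03), DHRS11 (-0.85), STC1 (-0.85), THBS1 (0.76) and UBBP1 (0.75). With Thiamet-G they were RAB40B (-0.88), RNFT2 (-0.75), ACOT13 (-0.69), SERPINI1 (-0.67), MARCHF2 (-0.61), WNT6 (0.56), THBS1 (0.53), SNORA21 (0.51), EREG (0.50) and ADAMTS1 (0.50). CYP1A1, UBBP1, WNT6, SNORA21, EREG and THBS1 were not past the threshold at 48 h. Between 0 h arrays the SD over genes of the difference was 0.126 for 5SGlcNAc and 0.138 for Thiamet-G, and at 24 h it was 0.226 and 0.185. For Thiamet-G it was 0.194 at 4 h and 0.192 at 8 h.

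**Figure D3:**
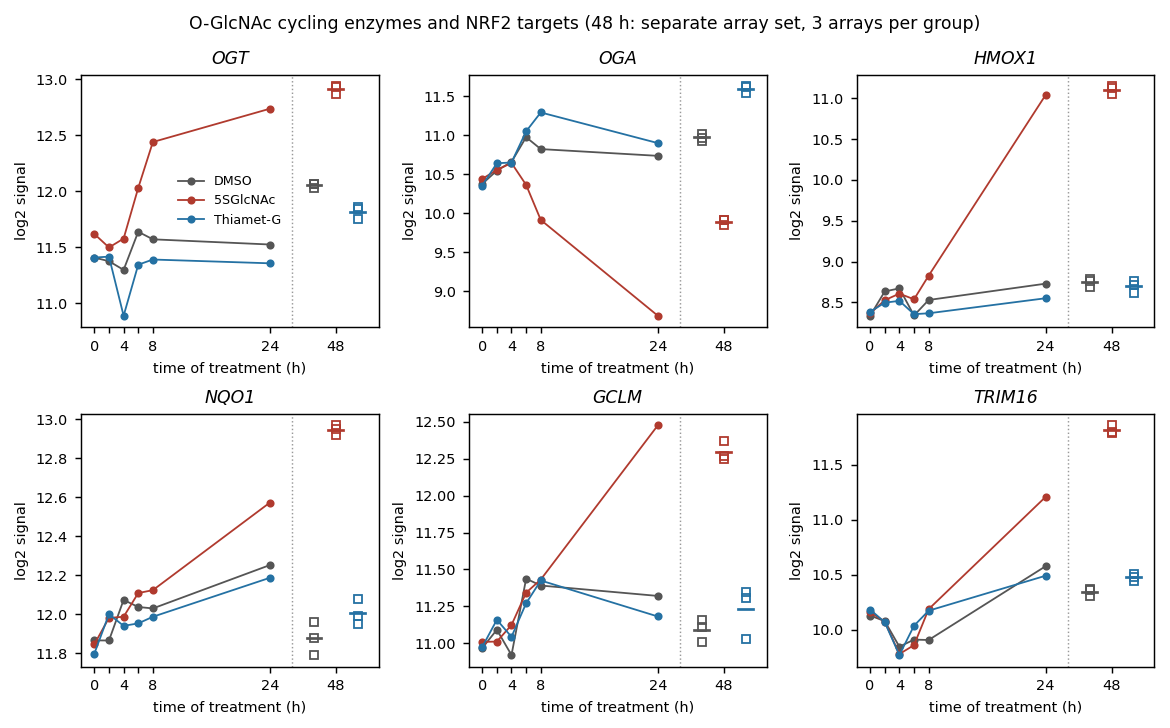
Log2 signal (y axis) of OGT, OGA and 4 NRF2 targets by time of treatment in hours (x axis), for DMSO (grey), 5SGlcNAc (red) and Thiamet-G (blue). Lines join single arrays of 0 to 24 h and squares are the 3 arrays per group of the separately processed 48 h set, with a bar at the mean; HMOX1 with 5SGlcNAc is at 8.83 at 8 h and at 11.04 at 24 h, and the OGT panel shows its brightest probe set only.

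Genes called at 48 h mostly differed the same way at 24 h. For 5SGlcNAc, 1033 of 1225 genes had the 48 h sign in the 24 h arrays (84.3%, exact 95% binomial interval 82.2 to 86.3, which treats genes as independent), against 59.3% at 0 h and 43.8% to 58.0% at 2 to 8 h. The share at 24 h was 91.1% of the 876 genes that fell and 67.3% of the 349 that rose, and for those that rose it was 65.0% at 2 h and 67.3% at 8 h, against 38.1% at 0 h. The 5SGlcNAc array of 24 h had a median of 7.43 over probe sets, against 7.51 with DMSO. With the single arrays centred on their medians, a setting added after the data were seen, the shares at 24 h were 82.3% and 80.2%, and 69.6% at 8 h for those that rose. For Thiamet-G the share was 93.5% at 24 h (90.7 to 95.7), against 60.4% at 0 h, 76.0% at 8 h and 80.6% at 4 h, where the ACTB signal of the DMSO and Thiamet-G arrays stood apart. Of the 57 genes that rose with Thiamet-G, 29.8%, 86.0%, 57.9%, 64.9%, 93.0% and 86.0% had the 48 h sign at 0, 2, 4, 6, 8 and 24 h, and of the 360 that fell 65.3%, 51.1%, 84.2%, 62.2%, 73.3% and 94.7%. The median difference in the 48 h direction at 24 h was 0.20 for 5SGlcNAc and 0.22 for Thiamet-G, at percentile 100 of 10000 random lists matched on expression. The 0 h shares lay above an even split too, with medians of 0.02 and 0.03 at percentiles 99.9 and 97.6, so a high percentile alone does not mark a time. The NRF2 list median at 24 h was 0.16 with 5SGlcNAc, with 28 of 36 members higher (percentile 100), and 0.05 at 6 h (percentile 87.2).

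**Figure D4:**
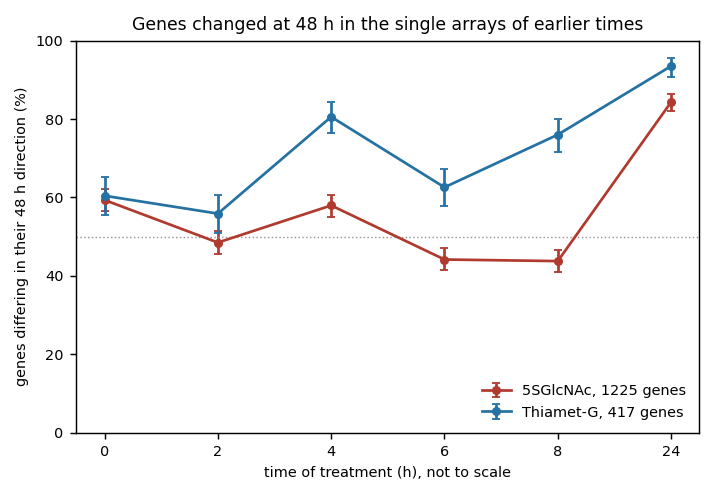
Share of genes called at 48 h (y axis, percent, with exact 95% binomial intervals) whose single-array difference from DMSO had the 48 h sign, by time in hours (x axis), for 1225 genes of 5SGlcNAc (red) and 417 of Thiamet-G (blue). The dotted line marks an even split, and at 24 h the shares are 84.3% and 93.5%.

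Averaged over 2 to 24 h, HMOX1 with 5SGlcNAc lay 0.53 ± 0.298 (SE) above DMSO and NQO1 0.10 ± 0.061, and neither passed. GCLM (0.24), GCLC (0.07), TXNRD1 (0.07), SLC7A11 (0.07), NFE2L2 (0.07), KEAP1 (0.06), TXNIP (-0.08), OGA (-0.71) and the brightest OGT probe set (0.57) did not pass either. limma called 0 genes for 5SGlcNAc against DMSO, with 524 at an unadjusted p under 0.05, and the smallest adjusted p was 0.161, for ZNF551 (-0.33). The next smallest p belonged to GRAMD1C (-0.31), UGT8 (-0.30), BCOR (-0.30) and ALMS1 (-0.26), and on the higher side to CIDEB (0.22), GABRD (0.27), SLC2A11 (0.35), EPB41L4A-DT (0.34) and KCNMB3 (0.26). For Thiamet-G against DMSO limma also called 0 genes, with 1111 at an unadjusted p under 0.05. The smallest p belonged to CHML (0.35, adjusted p = 0.114), KANK1 (0.34), CITED2 (0.36), EREG (0.43) and BMP4 (0.25), and to ZNF329 (-0.41), SUSD6 (-0.30), CDKN1A (-0.41), the sialidase NEU1 (-0.31) and CFAP44 (-0.34). Leaving out dim genes gave 10 genes for Thiamet-G trend and robust variance gave 20 and adding the 0 h arrays gave 2. With Thiamet-G, OGT differed by -0.20, OGA by 0.16, NQO1 by -0.04, HMOX1 by -0.12, GCLM by -0.02, GCLC by -0.16, TXNRD1 by -0.03, SLC7A11 by 0.06, NFE2L2 by 0.04, KEAP1 by 0.01 and TXNIP by -0.03.

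Between the inhibitors 31 genes passed over 2 to 24 h, 10 higher and 21 lower with 5SGlcNAc. Higher were the brightest OGT probe set (0.78 ± 0.144 SE, adjusted p = 0.0483), which other OGT probe sets opposed at 24 h, ZNF329 (0.42), FRAT1 (0.40), KLHL41 (0.38) and the cytokine TNFSF9 (0.36). Lower were the epithelial transcription factor EHF (-0.57), SPRY1, an inhibitor of receptor tyrosine kinase signalling (-0.55), the corepressor BCOR (-0.49), ZNF551 (-0.48) and HIVEP1 (-0.45). NEU1 (0.35) was the only called member of the lysosome list. OGA (-0.87), HMOX1 (0.65), GCLM (0.26), GCLC (0.23), NQO1 (0.14), TXNRD1 (0.10), SLC7A11 (0.01), NFE2L2 (0.04), KEAP1 (0.05) and TXNIP (-0.05) did not pass. The count rests on single times: without 2, 4, 6, 8 or 24 h it was 9, 1, 0 (limma, with 1245 at an unadjusted p under 0.05), 3 or 3, and without the DMSO array of 4 h, whose ACTB signal stood apart, it was 18. With the 0 h arrays added it was 82, without dim genes 166, with trend and robust variance 180 and without the time block 1.

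Gene lists over 2 to 24 h passed at the preset correlation only. With 5SGlcNAc against DMSO the NRF2 list had a median of 0.06 (adjusted p = 0.000835, and adjusted p = 0.669 with an estimated correlation), and without the 24 h arrays its median was 0.02 and none of the 32 lists passed. Without the time block 2 lists passed. Replication (median -0.05), mitosis (-0.04) and ERK feedback (-0.06) shifted down (adjusted p = 0.000579, 0.0346 and 0.0239, and adjusted p = 0.716, 0.777 and 0.669 with an estimated correlation). With Thiamet-G 7 lists passed. ER chaperones (-0.05), cholesterol (-0.06), lysosome (-0.05) and metallothioneins (-0.07) shifted down, and mitosis (0.05), ERK feedback (0.07) and ribosome biogenesis (0.04, and 0.02 after quantile normalization) up, each at adjusted p = 0.570 with an estimated correlation. Without the DMSO array of 4 h, the number was 4, without the time block 3, and without 2, 4, 6, 8 or 24 h it was 5, 3, 4, 2 or 4. After quantile normalization mitosis and ERK feedback no longer passed, and after median centring cholesterol and metallothioneins did not. Between the inhibitors NRF2 (0.08), cholesterol (0.07) and lysosome (0.05) lists were higher and replication (-0.06), mitosis (-0.06) and ERK feedback (-0.13) lower with 5SGlcNAc. Their adjusted p = 0.500, 0.500, 0.500, 0.806, 0.500 and 0.431 with an estimated correlation. The NRF2 list between inhibitors lost its call without 24 h too (median 0.06). In the lists that passed, no member was called over all genes apart from NEU1 between the inhibitors. Adjusted over the list alone, 1 ER chaperone and 1 lysosome gene fell and 1 ERK feedback gene rose with Thiamet-G. Between the inhibitors, 3 ERK feedback genes were lower, and 1 cholesterol and 1 lysosome gene higher, adjusted over the list alone.

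Changes with time were tested over the 3 series together, DMSO included, and not within a series. At 2 h the immediate early genes FOS and EGR1 rose by 1.95 ± 0.246 and 1.79 ± 0.172 (SE, n = 3 series) and ATF3 by 1.65, with ID4 by 0.94. CDC42EP2 fell by 0.66, DUSP4 by 0.65, NABP1 by 0.64 and MYC by 0.64. At 4 h the interferon-induced genes IFIT1 and OASL rose by 1.94 and 1.56, with ATF3 at 1.70 and EGR1 at 1.54, while HAS2, a hyaluronan synthase, fell by 1.53, NDP by 1.31, E2F5 by 0.77 and HS3ST1 by 0.72. At 6 h IFIT1 was up by 2.32, the heat shock gene HSPA6 by 1.94, OASL by 1.76 and IFIT2 by 1.36, and NDP was down (-1.27), as were HAS2 (-0.97), SLC14A1 (-0.87) and ST6GALNAC5 (-0.86). At 8 h IFIT1 was up 2.83-fold, the receptor FGFR3 by 0.91 on the log2 scale, GCH1, which starts tetrahydrobiopterin synthesis, by 0.90 and OASL by 0.88, and GDF15 was down (-1.01), with HAS2 (-0.88), SLC14A1 (-0.85) and NDP (-0.81). At 24 h IFIT1 (1.27), IL11 (1.12), the histone gene H2AC6 (0.87) and ADAMTS3 (0.81) were up, and AGR2 (-1.58), GDF15 (-1.57), PTGS2 (-1.45) and TFF1 (-1.40) were down. For GDF15 a dimmer probe set differed by 0.08 at 24 h.

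**Figure D5:**
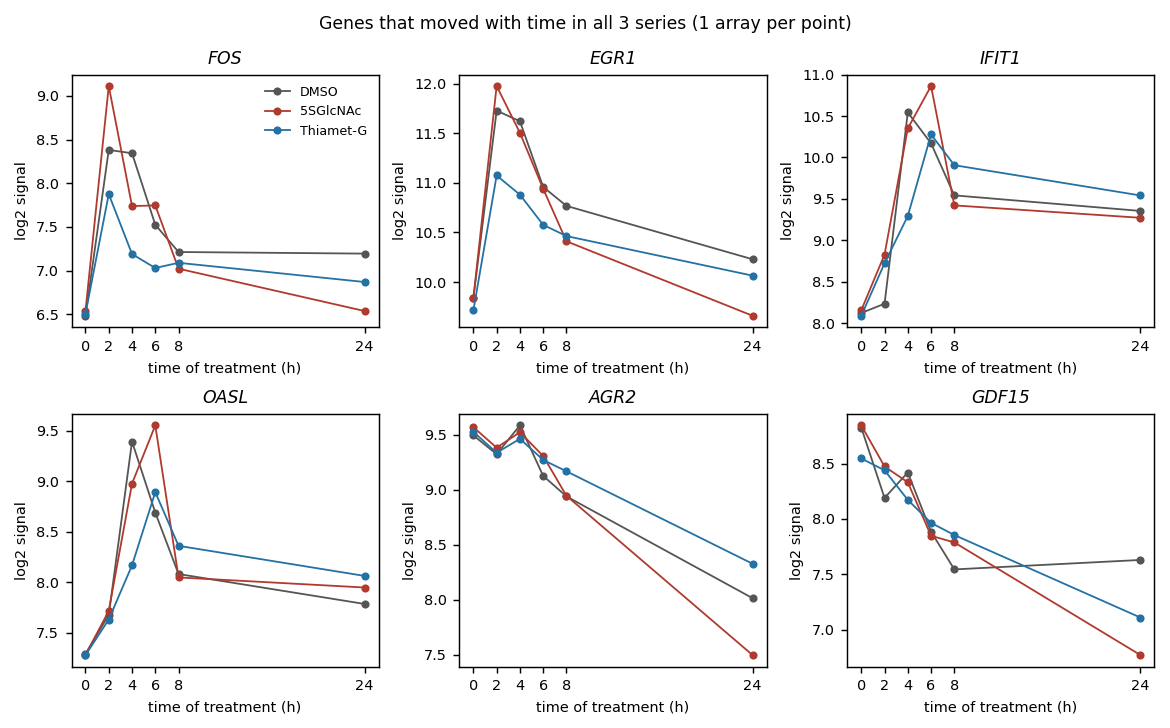
Log2 signal (y axis) of 6 genes by time of treatment in hours (x axis) in the DMSO (grey), 5SGlcNAc (red) and Thiamet-G (blue) series, 1 array per point. FOS peaks at 2 h in each series, IFIT1 is highest at 4 h with DMSO and at 6 h with either inhibitor, and AGR2 is lowest at 24 h in each.

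Gene lists at 2 to 8 h against 0 h were tested after the data were seen. At 2 h, 4 of 13 ERK feedback genes fell and none rose (8 and 0 adjusted over the list alone). They were DUSP4, the phosphatase DUSP5 (-0.46), SPRY2 (-0.42) and PHLDA1 (-0.37), chosen after their values were seen. The list median was -0.24 (adjusted p = 2.33e-11, and 0.0167 with an estimated correlation). At 4 h, 8 of 26 interferon genes rose and none fell (9 and 0 adjusted over the list alone; median 0.17), and 7 of 23 immediate early genes rose (9 rose and 2 fell adjusted over the list alone). Their adjusted p was 1.56e-05 and 1.69e-05, and adjusted p = 0.491 for both with an estimated correlation. The ACTB signal of the DMSO and Thiamet-G arrays stood apart at 4 h. Of the 26 interferon genes, 1 was higher with Thiamet-G than with DMSO (median -0.33) and 6 with 5SGlcNAc (median -0.08). None of 10 haematopoietic markers passed at 4 h, where all 10 were higher (median 0.11, adjusted p = 0.197). Immediate early genes also passed at 2 h and 6 h (adjusted p = 0.0213 and 0.00918, and adjusted p = 0.661 and 0.588 with an estimated correlation). At 6 h, 9 interferon genes had risen and none had fallen, among them IFIT1, OASL, the RNA sensor IFIH1 (1.22) and IFIT3 (1.18), the last pair chosen after their values were seen (10 and 1 adjusted over the list alone; adjusted p = 1.77e-06, and adjusted p = 0.588 with an estimated correlation). The luminal list shifted down at 2, 4, 6 and 8 h, with medians of -0.08, -0.12, -0.09 and -0.19. Of its 18 members 2, 3, 3 and 8 had fallen and none had risen (2, 4, 6 and 9 falls and no rise adjusted over the list alone). Its adjusted p was 0.00939, 0.00832, 0.00918 and 0.000111, and adjusted p = 0.410, 0.491, 0.588 and 0.495 with an estimated correlation. The DNA replication list shifted up at the same 4 times, with medians of 0.13, 0.13, 0.15 and 0.16. Of its 30 members 0, 1, 5 and 7 had risen in limma and none had fallen, and adjusted over the list alone 1, 3, 10 and 13 had risen and 1 had fallen, at 6 h. Its adjusted p was 1.65e-12, 0.000194, 1.18e-07 and 1.69e-07, and adjusted p = 0.271, 0.491, 0.588 and 0.527 with an estimated correlation. Members that had risen at 8 h included CCNE2 (0.64), PCNA (0.41) and MCM4 (0.37), chosen after their values were seen. In all 9, 8, 7 and 6 lists passed at 2, 4, 6 and 8 h, and with an estimated correlation 1, 0, 0 and 0. Immediate early genes and proteasome subunits at 2 h and cholesterol at 8 h lost their calls after quantile normalization, and ribosome biogenesis at 8 h after median centring.

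At 24 h, 10 lists had shifted from 0 h. In the NRF2 list 12 of 36 members rose and the transporter gene ABCC3 fell (-0.43, named after its value was seen; 16 and 1 adjusted over the list alone), with TXNRD1 higher by 0.71, SLC7A11 by 0.70 and GCLM by 0.68. Of the 3 series, 1 was 5SGlcNAc. With DMSO alone, TXNRD1 went from 12.52 to 13.19 and GCLM from 10.97 to 11.32. In the matrix list CDH1 fell by 0.84, COL6A1 by 0.65 and COL6A3 by 0.65, and 9 of 28 fell and none rose (11 and 0 adjusted over the list alone). In the NF-kB list 7 of 20 fell and IL11 rose (8 and 1 adjusted over the list alone), with PTGS2 and CXCL1 (-0.58) lower. Among luminal markers TFF1, CDH1 and MUC1 (-0.58) fell; 7 of 18 fell and EPCAM (0.22) and CLDN4 (0.30), named after their values were seen, rose. Adjusted over the list alone, 7 fell and 3 rose. Metallothioneins and zinc genes shifted up, with SLC30A1 higher by 0.29, MT1H by 0.27 and MT1G by 0.26 (6 of 9 rose, also adjusted over the list alone). A dimmer MT1G probe set differed by -0.05. Mitotic genes shifted up, with BUB1 by 0.31, CENPE by 0.30 and DLGAP5 by 0.25 (3 of 31, also adjusted over the list alone). Heat shock genes shifted up with DNAJB4 by 0.43 and HSPA4 by 0.19 (2 of 15, and 4 adjusted over the list alone), and proteasome genes with PSMD12 by 0.28, PSMD11 by 0.26 and PSMC2 by 0.19 (3 of 28, also adjusted over the list alone). Ribosome biogenesis shifted down, with RRP12 at -0.28, NOP16 at -0.25 and PUS7 at -0.23 (4 of 19 fell, and 5 adjusted over the list alone), and MondoA targets with TXNIP at -0.40 and G6PC3 at -0.24 (2 of 5, and 3 adjusted over the list alone). In the order NRF2, matrix, NF-kB, luminal, metallothionein, mitosis, heat shock, proteasome, ribosome biogenesis and MondoA, camera gave adjusted p = 1.53e-06, 4.18e-06, 0.00246, 0.0151, 0.000833, 0.000772, 0.0140, 0.00246, 0.00532 and 0.0276. With an estimated correlation these became adjusted p = 0.247, 0.247, 0.406, 0.406, 0.406, 0.491, 0.505, 0.505, 0.491 and 0.247.

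At 2, 4, 6, 8 and 24 h, 61, 392, 537, 761 and 1193 genes differed from 0 h (limma). Rises numbered 25, 159, 272, 463 and 578, and falls 36, 233, 265, 298 and 615. That split depends on scaling at 2 h, with 31 rises and 27 falls after median centring, and at 8 h, with 459 and 458 after quantile normalization. At 6 h and 24 h, 49.3% and 51.6% of calls fell as deposited, too near an even split to give a direction. The counts depend on all 3 series: without the DMSO series they were 0, 0, 3, 1 and 325, without the 5SGlcNAc series 6, 4, 22, 112 and 266, and without the Thiamet-G series 28, 151, 104, 85 and 426. Where 0 genes passed in limma, at 2 h and 4 h without the DMSO series, 785 and 1309 had an unadjusted p under 0.05. Without dim genes the counts at 2, 6 and 8 h were 101, 870 and 1205, and with trend and robust variance 92, 852 and 1184. At 4 h the count was 125 without the DMSO array of that time.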

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

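The tests of explanations were chosen only after the results were seen, as was the test of 48 h effects against 2 to 24 h effects; the regrouping of arrays was planned.

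The effect of 5SGlcNAc differed between 48 h and the mean of 2 to 24 h for 213 genes (limma, adjusted, a difference of effects over 24 arrays of the separately processed sets). Among the NRF2 targets always named, the 48 h effect was larger by 1.83 for HMOX1 (adjusted p = 0.0268), 0.97 for NQO1 (1.71e-05), 0.96 for GCLM (0.0449), 0.88 for SLC7A11 (0.00406), 0.65 for TXNRD1 (0.00843) and 0.53 for GCLC (0.00843). Of 3151 probe sets that named no gene or several, 106 changed with 5SGlcNAc at 48 h, 30 up and 76 down, and 1 changed with Thiamet-G. No group held 4 to 10 arrays, so no array was tested against its group for lying apart.

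More genes fell than rose at 48 h with either inhibitor. A DMSO array out of place was argued against, since without any 1 DMSO array at least 74.6% of calls fell with 5SGlcNAc and 85.1% with Thiamet-G. Scaling between arrays was argued against as the whole cause for Thiamet-G, where 74.5% fell after median centring (68.4 to 79.9, binomial 95% interval). Such an interval treats genes as independent although they come from the same arrays, so it does not measure the spread between arrays. Falls went from 360 to 175 and rises from 57 to 60, so scaling may account for part. For 5SGlcNAc the share after median centring was 58.7% (55.8 to 61.5). That spans the bound of 60%, set for both inhibitors after the shares were seen, so scaling stays open there. Centring used the medians of all probe sets. Over the tested genes the median change as deposited was 0.01 with 5SGlcNAc and -0.01 with Thiamet-G. Centring may thus itself have lowered both shares, and they cannot show how much scaling accounts for. Without DMSO, 49.7% of calls were lower with 5SGlcNAc than with Thiamet-G, so high values of all DMSO arrays and an effect common to both inhibitors cannot be told apart, because both use the same 3 DMSO arrays.

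No gene passed over 2 to 24 h for 5SGlcNAc against DMSO (limma; 524 had an unadjusted p under 0.05), although 1225 passed at 48 h. A wider error of most of those 1225 genes was argued against, since the median ratio of their standard errors, 2 to 24 h over 48 h, was 1.19. For 238 genes the ratio was over 1.5, such as HMOX1 (0.298 over 0.0513). The error over 2 to 24 h also holds any change of the effect with time. HMOX1 differed from DMSO by 2.31 at 24 h, against a mean of 0.53 over 2 to 24 h. For such genes a wider error and a late effect therefore cannot be told apart. A late effect averaged over 5 times may account for the 876 genes that fell at 48 h, whose median difference in that direction was at most 0.0354 at 2 to 8 h and 0.237 at 24 h, or 0.0417 and 0.158 with each array centred on its median. It stays open for the 349 that rose, at most 0.0469 and then 0.0704, or 0.0539 and 0.15 centred, since their 0 h arrays differed by -0.0248 and -0.0215; the lower value at 24 h as deposited goes with the median of the 5SGlcNAc array of 24 h, 7.43 against 7.51 with DMSO. First versions of both tests, which took the error of all genes and pooled both directions (0.0218 at most against 0.20), and the late test without centring were replaced after their results were seen.

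Over the 3 series together, 8 of 26 interferon list members rose at 4 h and 9 at 6 h, with no test within a series, and single arrays differed: 1 of 26 was higher with Thiamet-G than with DMSO at 4 h (median -0.33) and 24 of 26 with 5SGlcNAc at 6 h (0.20). RNA quality of the 4 h arrays was argued against as the whole cause, since those 9 members passed at 6 h, where the list median was 0.1997 (adjusted p = 1.77e-06, and adjusted p = 0.588 with an estimated correlation), and it stays open for the size of the rise at 4 h. RNA of blood cells stays open, since the haematopoietic list median was 0.0309 at 6 h but 0.11 at 4 h, with 10 of 10 members higher (camera adjusted p = 0.197). Mean levels of these markers ran from 3.84 (PTPRC) to 7.38 (HBB), under the median of 8.17 over all genes. Small shifts of such dim markers cannot decide for or against blood cells. Low values of the 0 h arrays were argued against, since 5 of 26 members rose from 2 h to 6 h, a contrast without 0 h; first versions of the last tests, with the 8 h interferon median and with the haematopoietic median of 6 h alone, were replaced after their results were seen. No biological explanation was tested.

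At 48 h and for each time against 0 h there are 10 splits of the 6 arrays, too few for a share under 0.05. The real splits gave 1225, 417 and 1634 genes at 48 h, in the order 5SGlcNAc against DMSO, Thiamet-G against DMSO and 5SGlcNAc against Thiamet-G, and 61, 392, 537, 761 and 1193 genes at 2, 4, 6, 8 and 24 h. The highest of the other splits was 0 genes in limma for each. For lists at 48 h the real and highest other numbers were 13 and 12, 6 and 2, and 14 and 10. For the NRF2 list median they were 0.30 and 0.125, 0.005 and 0.0383, and 0.34 and 0.152. In these designs 1 split, the real one, was as large, apart from the NRF2 median with Thiamet-G, where 9 of 10 were. Other splits passed up to 12 lists with 0 genes. Each of them still holds unequal numbers of treated arrays on its sides and so keeps part of a treatment effect. Their counts of lists at the preset correlation therefore do not show what chance gives.

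Over 2 to 24 h, 100 splits were drawn. For the 31 genes between the inhibitors, 1 split, the real one, gave as many and the highest other was 1. The splits moved arrays across times although the fit blocks on time, so they cannot exclude chance. For 5SGlcNAc and Thiamet-G against DMSO limma found 0 genes (524 and 1111 at an unadjusted p under 0.05), so all 100 splits gave as many by construction and the comparison says nothing about chance; the highest others were 0 and 1. Chance cannot be excluded for the lists and the NRF2 medians either. For 4, 7 and 6 lists, 43, 11 and 22 splits gave as many, with a highest other of 10 in each contrast. For NRF2 medians of 0.06, -0.01 and 0.08, 18, 58 and 6 splits gave a size as large, with highest others of 0.0878, 0.0886 and 0.0987.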

How the results depend on the processing

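The settings were planned, apart from the fits without the DMSO array of 4 h and the centring of single arrays for shares by direction, which were chosen after the data were seen. Of 342 values of the main results under alternatives, 254 kept their direction, their side of the threshold or a count within 1.5 times, and 88 did not. Of 3387 values of named genes, 3016 kept their side of the threshold, 343 no longer passed and 22 newly passed. Another 6 reversed in sign with at least 1 of the 2 fits past the threshold. A change of sign where neither fit passed was counted as kept, for named genes and for list medians. The NRF2 list with 5SGlcNAc at 48 h passed in every setting run, with medians of 0.27 to 0.33. Signal over background limits dim genes, whose changes RMA compresses, and a filter on them alters the number of genes adjusted for. For the other settings the cause was not tested.

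With the mean of probe sets, OGT reversed to -0.43, 0.0553 and -0.49 at 48 h for 5SGlcNAc against DMSO, Thiamet-G against DMSO and 5SGlcNAc against Thiamet-G, because its probe sets differ in sign. APOBEC3G reversed to 0.0767 between the inhibitors in the fit on only the arrays of the 2 groups, and without probe sets of shared sequence GDF15 and MT1G reversed to 0.0812 and -0.0534 at 24 h against 0 h; each then rested on another probe set.

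With an estimated correlation, 4, 0 and 3 lists passed at 48 h in that order of contrasts and 0, 0 and 0 over 2 to 24 h, where the NRF2 medians of 0.0591 and 0.0836 no longer passed. Quantile normalization gave 3 lists for Thiamet-G at 48 h, 71 genes shared in direction and a same-sign share at 24 h of 79.5% for 5SGlcNAc. Median centring gave 235 genes for Thiamet-G at 48 h, and of the single arrays alone gave same-sign shares at 24 h of 80.2% and 82.3% for genes that rose and fell with 5SGlcNAc. Only the arrays of the 2 groups gave 129 genes for Thiamet-G and 1069 between the inhibitors. Leaving out dim genes gave 949 for Thiamet-G at 48 h, 10 for Thiamet-G and 166 between the inhibitors over 2 to 24 h, and 101, 870 and 1205 at 2, 6 and 8 h against 0 h. Trend and robust variance gave 925, 20, 180, 92, 852 and 1184 for the same results.

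Over 2 to 24 h, without the time block 2 and 3 lists passed for 5SGlcNAc and Thiamet-G, and 1 gene between the inhibitors. With 0 h arrays added, 2 genes passed for Thiamet-G and 82 between the inhibitors. With only 2 to 8 h, 0 lists passed for 5SGlcNAc (NRF2 median 0.0244), 4 for Thiamet-G, and 3 genes between the inhibitors (NRF2 median 0.0587). Without the DMSO array of 4 h, 4 lists passed for Thiamet-G, 18 genes between the inhibitors and 125 genes at 4 h against 0 h.

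Leaving out 1 array at 48 h gave 679 to 984 genes for 5SGlcNAc, 101 to 683 for Thiamet-G, 926 to 1937 between the inhibitors, and 2 to 7 lists for Thiamet-G; the 683 and 1937 were without Thiamet-G replicate 2. Leaving out 1 time gave 0 to 5 lists for 5SGlcNAc (NRF2 median 0.0244 to 0.0808), 2 to 5 lists for Thiamet-G, and 0 to 9 genes between the inhibitors (NRF2 median 0.0587 to 0.0817). Leaving out 1 series gave 0 to 28, 0 to 151, 3 to 104, 1 to 112 and 266 to 426 genes at 2, 4, 6, 8 and 24 h. Where limma called 0 genes, 1245 (between the inhibitors), 785 (2 h) and 1309 (4 h) had an unadjusted p under 0.05.

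The replicate number does not pair the 48 h arrays: same-number correlations of deviations ran from -0.33 to 0.17, and not every sample correlated best with its own number. With the replicate number as a block, the pairing fit gave 895, 186 and 1162 genes, 47 and 10 shared genes of the same and opposite direction, and a same-sign share of 87.0% for 5SGlcNAc at 24 h.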

Other observations

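The patterns here were noticed in the data, and all genes named were chosen after their values were seen.

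With 5SGlcNAc at 48 h, genes of several further lists changed. In the hypoxia list the angiogenic factor VEGFA fell by 0.60, the crosslinking enzyme LOX fell by 0.44 and BHLHE40 fell by 0.34, while the peptide hormone gene ADM rose by 0.57, and 15 of 19 members did not pass; adjusted over the list alone, 5 fell and 2 rose (camera adjusted p = 0.326). In the circadian list NPAS2, a partner of BMAL1, fell by 0.73. BHLHE40 was the other of its 15 members that fell, and 2 fell adjusted over the list alone (adjusted p = 0.138). Among p53 targets the DNA damage binding gene DDB2 fell by 0.50, the stress cytokine GDF15 fell by 0.59 and CCNG1 fell by 0.29, while GADD45A rose by 0.35 and AEN by 0.23; adjusted over the list alone, 4 fell and 3 rose (adjusted p = 0.575). In the ATF4 list DDIT4, an inhibitor of mTORC1, fell by 0.69 and PHGDH, the first enzyme of serine synthesis, fell by 0.30, while ATF3 and SLC3A2 (0.27) rose; adjusted over the list alone, 5 fell and 4 rose (adjusted p = 0.809). SLC3A2 encodes the heavy chain that pairs with SLC7A11. SREBF1, a regulator of lipid synthesis, fell by 0.61 and the desaturase SCD fell by 0.34, while malic enzyme ME1, which is also in the NRF2 list, rose by 0.57; adjusted over the fatty acid list alone, 4 fell and 1 rose (adjusted p = 0.326).

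With Thiamet-G at 48 h, the immediate early genes ATF3, EGR1 (0.36) and DUSP1 (0.31) rose and none of 23 fell. Adjusted over the list alone, 5 rose and 1 fell (adjusted p = 0.0911), and the median of -0.01 and mean of 0.05 differed in sign. ATF3, EGR1 and DUSP1 also rose with 5SGlcNAc, by 0.29, 0.21 and 0.22. Between the inhibitors ATF3 differed, and EGR1 and DUSP1 did not pass (limma, adjusted p = 0.0294, 0.0758 and 0.218). Low values of the shared DMSO arrays and an effect common to both inhibitors cannot be told apart here. With Thiamet-G the cell cycle inhibitor CDKN1A fell by 0.35 and SREBF1 fell by 0.32. Among ER chaperones SDF2L1 fell by 0.35, EDEM1 fell by 0.27 and PDIA4 fell by 0.20; adjusted over the list alone, 6 of 18 fell (adjusted p = 0.0532). None of these lists passed.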
